A study of Rattus with 9 samples.

How the data were processed

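Gene expression was measured by poly-A RNA sequencing in thoracic dorsal root ganglia of rats 8 weeks after myocardial infarction by coronary ligation (MI, n = 5) or sham surgery (n = 4). Each library came from a separate rat, per the labels, so the p-values reflect the spread between animals. In the deposited tables the MI group carries the name CHF; library names in the labels tie each column to its rat. All 9 RNA samples carry the same date in the deposited sample sheet, and no library batch is given in the sources used here.

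According to the series' design text, reads of 75 bp were demultiplexed with bcl2fastq 2.16.0.10, trimmed with cutadapt and aligned to the rn6 genome with STAR 2.3.0. Gene-level reads were then summarised against Partek 6.6 annotations. The deposited counts are whole-number read counts per gene, which the authors rounded from a table of estimated counts, per the file headers and the values. The deposited estimated counts held fractions in 967 of 17378 genes and differed from the rounded counts by at most 0.5. The deposited RPKM values are reads scaled by gene length and library size, computed by the authors. The authors' test table gives CPM values scaled by the trimmed mean of M-values (TMM), linear fold changes of MI over sham, mean log2 CPM and likelihood-ratio p-values, per the file headers. The deposited alignment summary gives reads and percent of reads in exons, introns and between genes. The deposited sample sheet gives the RNA integrity number, a score, together with RNA yield and absorbance ratios. A deposited note states a dispersion of 0.006.

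Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 11711 of 17378. Date-like identifiers, which spreadsheet software makes from gene symbols, occur 26 times and hold 0.241% of all counts. They stayed in the tests and are not named. Of the identifiers, 14979 equal a current RefSeq symbol (assembly GRCr8) and 1999 equal a synonym. That assembly differs from the authors' build, so no coordinates are given. Strand use in counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated. Copies of multigene families, such as RT1, haemoglobin and muscle myosin genes, may share reads and are uncertain.

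MI and sham were compared with an edgeR generalized linear model with TMM scaling, tagwise dispersions and a likelihood-ratio test, the test named in the series' design text. Adjustment was by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The edgeR quasi-likelihood test, which holds false calls closer to the nominal rate at this sample size, is given beside it. Adjusted p-values in the text are from the likelihood-ratio test unless another test is named. Expression levels are TMM-scaled CPM computed here. The SE beside a log2 fold change is the pooled standard error of the group difference in log2 CPM with a prior count of 2. It is not the error of the edgeR coefficient, so the ratio of log2 fold change to SE is not a test.

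Of 42 gene lists, 41 had at least 3 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The list score of a library is the mean of its members' log2 CPM centred over the 9 libraries; scores and library measures were compared by two-sided exact permutation tests over all 126 assignments, whose smallest possible p is 0.00794.

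The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 genes with the smallest p in each direction among genes past the threshold with mean log2 CPM of at least 1 and no placeholder symbol. With fewer than 20 such genes, the tested genes with the smallest p were added to reach 24 and are described as not past the threshold. For each list up to 4 members past the threshold were named, or else the member with the smallest p. Other genes named are said to have been chosen after their values were seen.

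Alternatives were the quasi-likelihood test, DESeq2 1.42.0, limma-voom with and without sample weights, 1 common dispersion, other scaling factors, other filters, a threshold of 0.10, the unrounded counts, log2(RPKM + 0.1) and log2(RPKM + 1) with limma, 1 surrogate variable (sva 3.50.0), the replicate number as a block, and fits without each library. A trended dispersion, and a fit without Sham 1 and MI 5, were added after seeing the data. The closing section gives their effects.

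The gene tests were tested on simulated data: 10 simulations of 11711 genes with the real means and library sizes and 200 changed genes, 5 libraries against 4. The likelihood-ratio test recovered 45.0% of genes changed 1.25-fold, 77.8% at 1.5-fold, 93.0% at 2-fold and 100% at 4-fold, and 12.2% of its calls were false. The quasi-likelihood test recovered 36.8%, 71.4%, 89.4% and 99.6%, with 6.1% false calls. With 1 common dispersion 35.6% of calls were false. With 200 changed genes the Benjamini-Hochberg cut-off is looser than with the 2 calls of the real data, so recovery may be lower here. Genes were drawn independently, so the shares of false calls do not cover structure shared by genes. Camera called a list shifted by 0.2 on the log2 scale in 10 of 10 simulations and 1 of 400 other lists. Those genes were simulated as independent, so this rate does not cover correlated genes; over other splits of the real libraries the median was 9 of 41 lists.

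Library totals ranged from 5656582 counts (Sham 1) to 6861355 (MI 5), with a median of 196 counts per tested gene and library. No libraries of a group agreed within counting noise; the smallest chi-square per degree of freedom between them was 2.81.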

Results

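Thoracic dorsal root ganglia hold the cell bodies of sensory neurons that innervate the chest organs, the heart included, together with satellite glia, Schwann cells, macrophages and vessels. Poly-A RNA from these ganglia was sequenced in 5 SD rats 8 weeks after myocardial infarction (MI) and in 4 rats after sham surgery. The comparison asked which transcripts of the ganglia differed after infarction. Total counts per library lay between 5656582 and 6861355. RNA integrity was 8.32 ± 0.217 (SD, n = 5) in MI and 8.33 ± 0.0957 (SD, n = 4) in sham rats. Among 14 measures of depth, composition and RNA quality, the smallest exact permutation p was 0.246, for the percent of reads between genes, and each was 1 after Benjamini-Hochberg adjustment. The first principal component held 19.7% of the variance and gave an exact p of 0.635 for the groups; of the first 4 components the fourth, with 11.7%, had the smallest exact p, 0.0397. Correlations between libraries had a median of 0.987 within groups and 0.987 between them.

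By the likelihood-ratio test, 2 genes passed the threshold with higher expression after MI, and none passed with lower expression. Cst3, which encodes cystatin C, a secreted inhibitor of cysteine proteases, stood at 1083 ± 153 CPM (SD, n = 5) in MI and 637 ± 131 CPM (SD, n = 4) in sham ganglia. Its fold change was 1.70 (log2 0.77, SE 0.17, edgeR adjusted p = 7.48e-05). Cbln4, which encodes cerebellin 4, a secreted synaptic organiser, stood at 18.9 ± 2.55 CPM (SD, n = 5) in MI and 10.9 ± 0.907 CPM (SD, n = 4) in sham ganglia. Its fold change was 1.73 (log2 0.79, SE 0.11, edgeR adjusted p = 7.48e-05). In both genes each of the 5 MI rats lay above all 4 sham rats, and both stayed past the threshold in all 9 fits that left out 1 library. Both were picked by p in these same libraries, so this is no separate support. Groups did not overlap for 1.74% of all tested genes, where chance gives 1.59%. The edgeR quasi-likelihood test called 0 genes, with adjusted p = 0.950 for Cst3 and 0.10 for Cbln4, and limma-voom also called 0. At an unadjusted p under 0.05 the quasi-likelihood test had 589 genes and the likelihood-ratio test 543, where chance gives 585.6. The count of 2 became 8 without Sham 3 (4 lower in MI) or without MI 1 (2 lower). It became 6 without MI 5 (3 lower) and 4 without MI 4 (0 lower). Of 100 splits of the libraries, the real one included, 69 gave at least 2 genes, so chance is not excluded for this count. Over 25 alternatives the adjusted p ranged from 5.12e-18 to 0.950 for Cst3 and from 2.07e-07 to 0.476 for Cbln4, and 5 of the 25 ended each call.

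**Figure D1:**
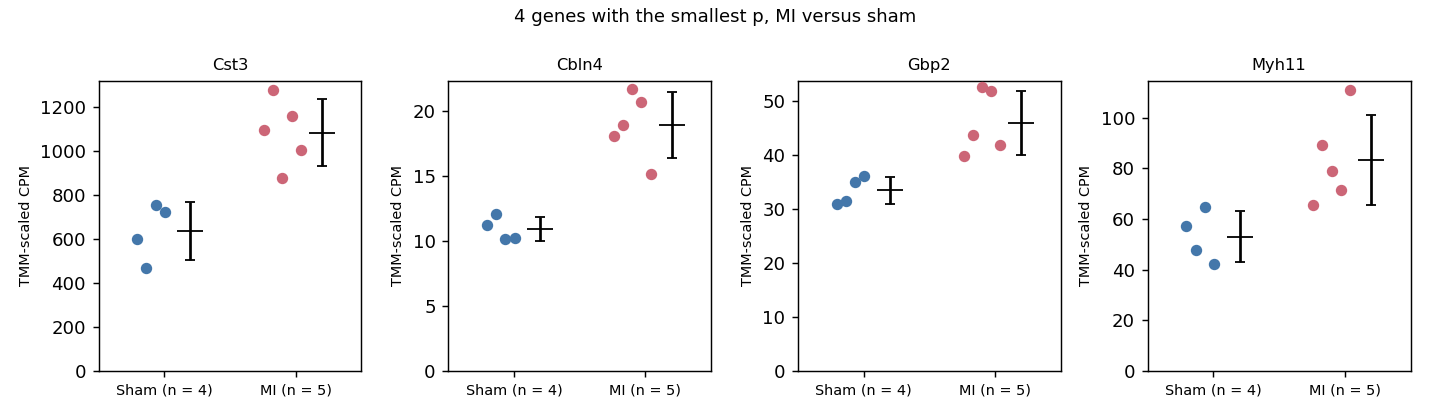
TMM-scaled CPM of Cst3, Cbln4, Gbp2 and Myh11 in each library, with points for rats and bars for the group mean ± SD (5 MI, 4 sham). All 5 MI rats lie above all 4 sham rats in each panel, in genes picked for the smallest p in these same libraries. Cst3 and Cbln4 passed the threshold, Gbp2 and Myh11 did not.

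Changes across the transcriptome were small, with a median absolute log2 fold change of 0.07 over 11711 genes. The next genes by p did not pass the threshold and are given as values. Among genes higher in MI were Gbp2, an interferon-induced GTPase, with log2 0.46 (SE 0.10, adjusted p = 0.0612), and Myh11, the smooth muscle myosin heavy chain, with log2 0.65 (SE 0.19, adjusted p = 0.0635). Cnn1, the smooth muscle protein calponin, had log2 1.27 (SE 0.37), and Kcnj8, a potassium channel subunit of vascular mural cells, had log2 1.08 (SE 0.16). Kcnj8 was low, at a mean of 2.87 CPM in MI and 1.34 CPM in sham ganglia. Myom2 had log2 0.49, Pygb, the brain form of glycogen phosphorylase, 0.20, Mcmdc2 0.66 and Rtn4ip1 0.51.

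Among genes lower in MI, Herpud1, a gene of endoplasmic reticulum stress, had log2 -0.37 (SE 0.10, adjusted p = 0.0940), and Ppp1r10, a nuclear regulator of protein phosphatase 1, had log2 -0.33 (SE 0.07, adjusted p = 0.125). Vgf, a neurosecretory peptide precursor, had log2 -0.57 (SE 0.19), and Cacna2d2, an auxiliary calcium channel subunit, had -0.32 (SE 0.07). Lss and Fasn, enzymes of cholesterol and fatty acid synthesis, had log2 -0.25 and -0.20. The potassium channel gene Kcnh6 had -0.36, the synaptic scaffold gene Dlgap3 -0.24 and the growth cone gene Basp1 -0.27. The sphingosine kinase gene Sphk1 had -0.38, Mpp2 -0.50 and Fndc7 -1.63, the last at a low mean of 0.949 CPM in MI and 2.98 CPM in sham. The transcription factor gene Elk1 had -0.78 (SE 0.27), set mostly by Sham 2 (39.84 CPM) and Sham 4 (40.14). Sham 1 (19.95) and Sham 3 (20.23) lay close to the MI rats, the highest of which was MI 4 (19.32). Fam111a had log2 -2.85 (SE 1.05), a value set by Sham 1 at 80.9 CPM against 2.53 to 3.16 in the other shams, and without Sham 1 it was 0.08.

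Of the 41 lists tested, 6 were shifted up and 7 down by camera with the preset correlation, and none of the 13 passed with an estimated correlation or by fry. Interferon-response genes, the targets of antiviral signalling, shifted up: 33 of 36 tested members were higher in MI, with a median log2 of 0.18 (camera adjusted p = 4.65e-07, and adjusted p = 0.538 with an estimated correlation). No member passed over all genes and 1, Gbp2, passed when adjusted over the list alone. Usp18 (log2 0.78) and Irf7 (log2 0.67), further members chosen after their values were seen, did not pass. Pericyte and smooth muscle markers shifted up, with 12 of 14 members higher and a median log2 of 0.33 (camera adjusted p = 3.58e-05, and adjusted p = 0.538 with an estimated correlation). No member passed over all genes and 5 passed adjusted over the list alone: Myh11, Cnn1, Kcnj8, and Acta2 (log2 0.81) and Mylk (log2 0.37), the last pair chosen after their values were seen.

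Macrophage markers shifted up, with 22 of 27 members higher and a median log2 of 0.18 (camera adjusted p = 3.60e-05, and adjusted p = 0.538 with an estimated correlation). No member passed over all genes or adjusted over the list alone; Siglec1, a sialic acid-binding receptor of macrophages, had log2 0.65. Complement genes shifted up, with 17 of 21 members higher and a median log2 of 0.17 (camera adjusted p = 1.68e-04, and adjusted p = 0.538 with an estimated correlation). None passed adjusted over the list alone, C2 had log2 0.32, and 3 members, C1qa, C1qb and C1qc, are also macrophage markers. Antioxidant and oxidative stress genes shifted up, with 18 of 28 members higher (camera adjusted p = 0.0286, and adjusted p = 0.538 with an estimated correlation), 0 past adjusted over the list alone, and the member with the smallest p, Cybb, an oxidant-producing NADPH oxidase subunit of phagocytes, at log2 0.43. Nuclear-encoded oxidative phosphorylation genes shifted up by a median log2 of 0.03, with 29 of 38 higher (camera adjusted p = 0.0286, and adjusted p = 0.776 with an estimated correlation), 0 past adjusted over the list alone, and Atp5o at log2 0.11. The antioxidant and oxidative stress call was lost without Sham 2 (adjusted p = 0.108), MI 1 (0.0619), MI 3 (0.0521) or MI 5 (0.0664), and the oxidative phosphorylation call without Sham 1 (0.256), Sham 2 (0.466), MI 3 (0.0578) or MI 4 (0.192).

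Cholesterol synthesis genes shifted down, with 18 of 22 members lower and a median log2 of -0.08 (camera adjusted p = 1.35e-04, and adjusted p = 0.614 with an estimated correlation). Of these, 2 passed adjusted over the list alone: Lss and Mvd (log2 -0.26), an enzyme of the mevalonate pathway chosen after its values were seen. Peptidergic nociceptor markers shifted down, with 10 of 11 members lower and a median log2 of -0.11 (camera adjusted p = 0.00576, and adjusted p = 0.538 with an estimated correlation). Trpa1, an irritant-gated cation channel, had log2 -0.40 and was the 1 member past adjusted over the list alone; without Sham 3 the list had an adjusted p of 0.0700. Schwann cell and myelin markers shifted down, with 19 of 22 lower and a median log2 of -0.09 (camera adjusted p = 0.00576, and adjusted p = 0.704 with an estimated correlation), 0 past adjusted over the list alone, and Cnp at log2 -0.16. That call was lost without Sham 1 (adjusted p = 0.152) or MI 1 (0.140).

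Circadian clock genes, a list fixed as a check of handling, shifted down, with 12 of 15 lower and a median log2 of -0.09 (camera adjusted p = 0.00995, and adjusted p = 0.538 with an estimated correlation), and all 5 MI scores lay below all 4 sham scores. None passed adjusted over the list alone, Usp2 had log2 -0.53, and without Sham 1 the adjusted p was 0.0765. The circadian score of MI 4 was -0.2987, far below the other MI rats at -0.043 to 0.02303. Calcium and HCN channels shifted down, with 18 of 21 lower and a median log2 of -0.08 (camera adjusted p = 0.0124, and adjusted p = 0.689 with an estimated correlation). Cacna2d2 was the 1 member past adjusted over the list alone, and the call was lost without MI 2 (adjusted p = 0.179) or MI 5 (0.0626). Extracellular matrix and fibroblast genes shifted down, with 18 of 31 lower and a median log2 of -0.07 (camera adjusted p = 0.0399, and adjusted p = 0.776 with an estimated correlation), 0 past adjusted over the list alone, and Col4a1 at log2 -0.17. That call was lost without Sham 1 (adjusted p = 0.325), Sham 3 (0.0880), MI 1 (0.670) or MI 4 (0.661). Proliferation genes shifted down, with 14 of 24 lower, a median log2 of -0.01 and a mean of -0.10 (camera adjusted p = 0.0434, and adjusted p = 0.669 with an estimated correlation), 0 past adjusted over the list alone, and Top2a, a DNA topoisomerase of dividing cells, at log2 -0.62. That call was lost without Sham 1 (adjusted p = 0.0765), Sham 3 (0.119), Sham 4 (0.178), MI 3 (0.351) or MI 4 (0.192).

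**Figure D2:**
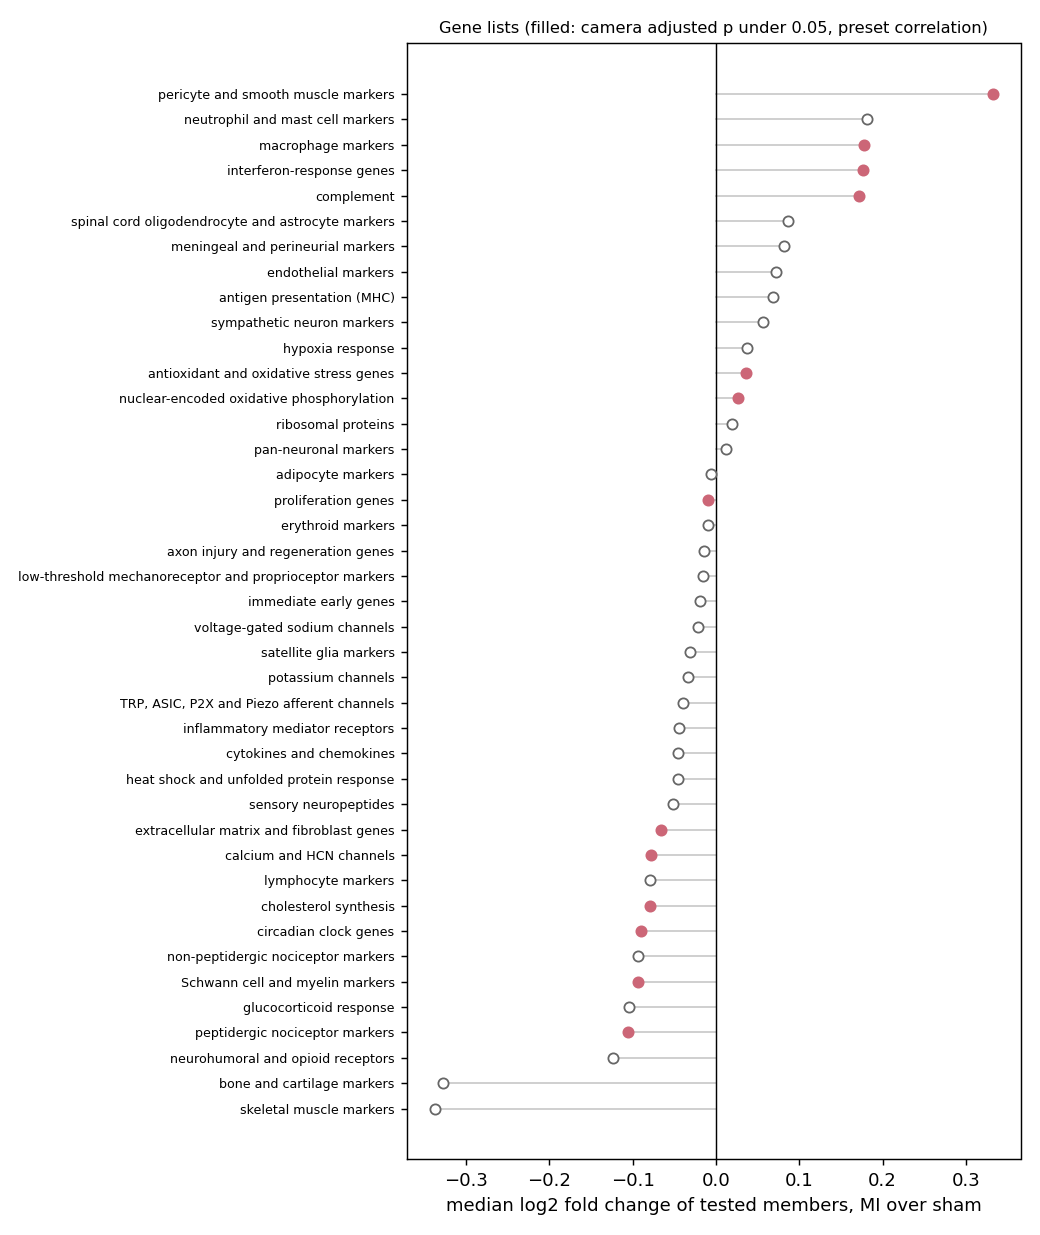
Median log2 fold change (MI over sham) of the tested members of each of 41 gene lists, with filled symbols for the 13 lists at a camera adjusted p under 0.05 with the preset correlation. Pericyte and smooth muscle markers (0.33) lie highest of the filled symbols, and none of the 13 passed with an estimated correlation.

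No shift past the threshold was found for the other lists of neuronal function, whose camera adjusted p-values and member with the smallest p were as follows. For sensory neuropeptides 4 of 11 members were higher (adjusted p = 0.557), with Nts at log2 0.48. For TRP, ASIC, P2X and Piezo afferent channels 9 of 23 were higher (0.371), with Trpa1 the 1 member past adjusted over the list alone. Inflammatory mediator receptors had 11 of 31 higher (0.115), with Ntrk2 at log2 -0.15, and neurohumoral and opioid receptors 10 of 27 (0.114), with Ednrb at -0.22. Voltage-gated sodium channels had 6 of 15 higher (0.557), with Scn1a at 0.12, and potassium channels 14 of 38 (0.0800), with Kcnc2 at 0.21. Axon injury and regeneration genes had 7 of 20 higher (0.442), with Smad1 at -0.15. Among neuron types, pan-neuronal markers had 11 of 19 higher (0.951), with Rbfox3 at -0.21, non-peptidergic nociceptor markers 5 of 14 (0.136), with Osmr at 0.44, and mechanoreceptor and proprioceptor markers 7 of 19 (0.403), with Ntrk2 lowest in p. Sympathetic neuron markers had 5 of 8 higher (0.557), with Maoa at 0.11.

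The same held for the other immune and tissue lists. Cytokines and chemokines had 7 of 18 members higher (camera adjusted p = 0.797), with Cxcl13 at log2 0.58, and antigen presentation genes 12 of 15 (0.136), with RT1-A1 at 0.35. Satellite glia markers had 4 of 15 higher (0.248), and Ednrb was the 1 member past adjusted over the list alone. Lymphocyte markers had 3 of 8 higher (0.442), with Cd4 at 0.32, neutrophil and mast cell markers 11 of 13 (0.442), with Hdc at 0.58, and endothelial markers 12 of 17 (0.309), with Erg at 0.42. Adipocyte markers had 5 of 11 higher (0.557), with 2 past adjusted over the list alone and Fasn smallest in p. Skeletal muscle markers had 2 of 13 higher (0.272), with Myh4 at -1.10, a value that turned to 0.51 without Sham 3. Spinal cord glia markers had 4 of 6 higher (0.588), with Aldh1l1 at 0.16, meningeal and perineurial markers 12 of 14 (0.878), with Krt19 at -0.31, bone and cartilage markers 1 of 7 (0.111), with Ibsp at -0.46, and erythroid markers 5 of 11 (0.721), with Hba2 at -0.44.

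Among the lists of handling and RNA quality, circadian clock genes passed, as given above, and the others did not. Immediate early genes had 7 of 17 members higher (camera adjusted p = 0.322), with Jund at log2 -0.14. Heat shock and unfolded protein genes had 10 of 21 higher (0.30), with Herpud1 the 1 member past adjusted over the list alone, and hypoxia genes had 11 of 18 (0.322), with Ddit4 at -0.27. Glucocorticoid-response genes had 5 of 18 higher (0.158), again with Ddit4 smallest in p, and ribosomal protein genes 29 of 37 (0.278), with Rpl6 at 0.08. The median, mean and test direction differed in sign for cytokines and chemokines, pan-neuronal, lymphocyte, adipocyte and erythroid markers. Of the sex-linked list only Eif2s3y (139 to 183 CPM) and Ddx3y (6.46 to 11.4 CPM) were tested, and both were detected in all 9 libraries.

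**Figure D3:**
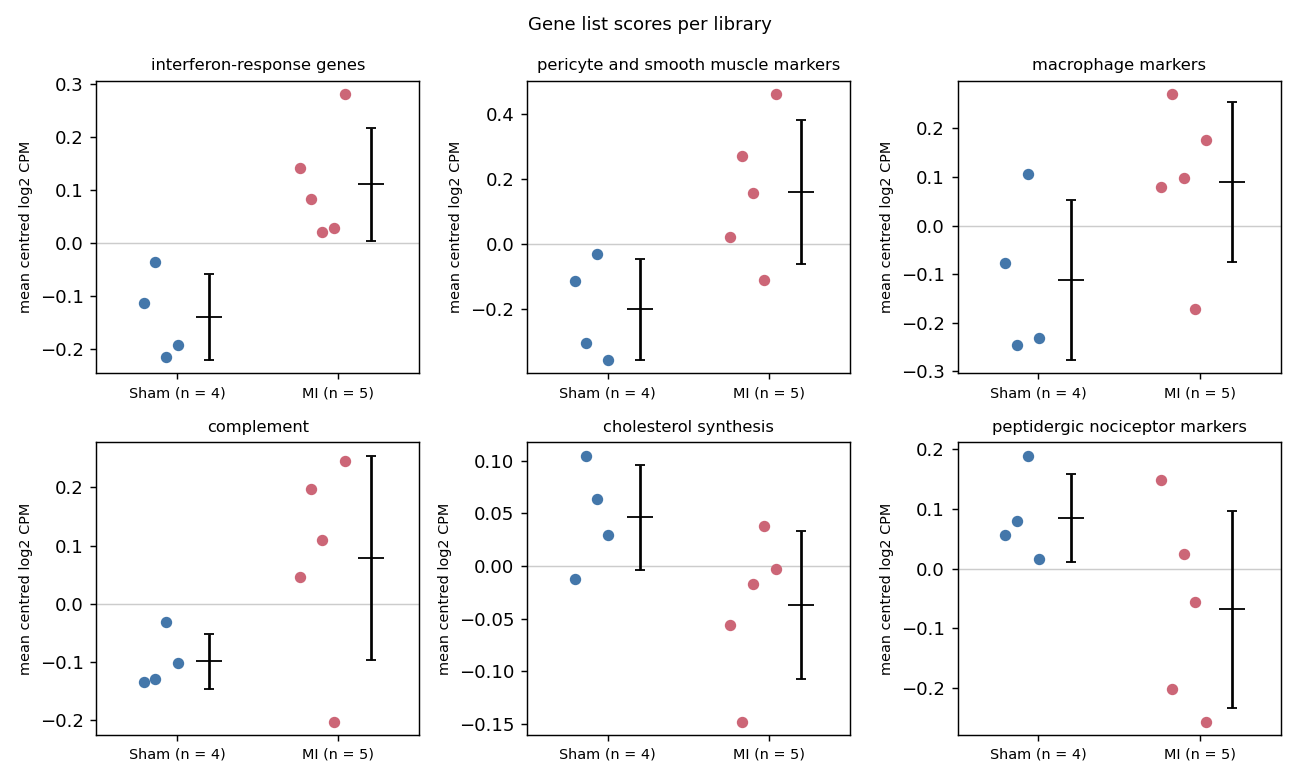
Mean centred log2 CPM of 6 gene lists in each library, with points for rats and bars for group means. Interferon-response scores of all 5 MI rats lie above all 4 sham rats, while pericyte and smooth muscle scores do so in 4 of 5.

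The authors' deposited table of the same comparison holds 60 genes past an adjusted p of 0.05, 34 higher and 26 lower in MI, and 72 past 0.10. Of the 60, 54 were tested here, and all 54 had the same direction. Both fits used the same libraries with TMM scaling, so the shared direction is no separate support. The likelihood-ratio test above called 2 of the 54, Cst3 and Cbln4, and the quasi-likelihood test 0, while a fit with 1 common dispersion called 47. The median tagwise dispersion of the 54 genes was 0.0485, against 0.00586 over all tested genes. In the authors' deposited table Fam111a had the smallest p, 2.12e-51.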

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

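No test here was chosen after the result was seen: each value below lay far from the rest of its group by a gap test on the highest or lowest library. That test picked 16 of 224 groups, where chance alone gives 11.2.

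Among genes, Fam111a stood at 80.88 CPM in Sham 1 against 2.528 to 3.162 in the other shams. Rbfox3, a neuronal nuclear protein gene, was low in Sham 1 at 37.59 CPM against 41.74 to 42.05. Herpud1 was low in MI 4 at 57.78 CPM against 71.61 to 74.36, and so was C2 at 30.64 CPM against 41.16 to 42.64. Elk1 was low in MI 3 at 13.35 CPM against 18.07 to 19.32. In MI 1, Osmr was high at 34.11 CPM against 16.49 to 17.74 and Mpp2 at 11.59 CPM against 7.854 to 8.493. In Sham 4, Ednrb was low at 66.11 CPM against 70.52 to 71.11, and Hdc at 0.1593 CPM against 1.422 to 1.603. In Sham 3, Smad1 was low at 34.45 CPM against 36.84 to 37.28, and Myh4, a fast skeletal muscle myosin gene, was high at 12.80 CPM against 1.069 to 1.912.

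The circadian clock score was low in MI 4 at -0.2987 against -0.043 to 0.02303 in the other MI rats. Sham 1 was the shallowest sham library, with 5657000 counts against 6306000 to 6313000, 11030000 alignments against 12180000 to 12350000, and 9359000 reads against 10390000 to 10460000. Sham 2 had 28.80% of reads between genes against 29.32% to 29.34% in the other shams.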

How the results depend on the processing

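The trended dispersion and the fit without Sham 1 and MI 5 were tests chosen after the result was seen; the other alternatives were fixed before. The 24 named genes kept their direction in 595 of 596 values; 42 passed the threshold that had not, and 10 no longer passed (Cst3 and Cbln4 in 5 each, under the quasi-likelihood, voom and RPKM fits). The exception was Fam111a, whose log2 fold change ranged from -3.23 to 0.084 over the fits without 1 library and turned without Sham 1. Myh4 ranged from -1.41 to 0.51 and turned without Sham 3. The named genes were picked by p in the same libraries that the alternatives refit, so their kept direction is no separate support. For the 13 shifted lists 253 of 312 values kept the call, 59 lost it and 0 turned direction. All 13 lost it with an estimated correlation and by fry, and the other alternatives used the preset correlation. These lists were also picked in the same libraries, so their kept calls and direction are no separate support. For the other 28 lists 597 of 671 values stayed, 29 passed and 45 turned direction. Why calls were gained, lost or turned was not tested, also where fewer samples or genes were fitted. The median log2 fold change of all genes was 0.0017 with TMM and at most 0.0124, with upper-quartile factors, under the other scalings. Libraries held a median of 196 counts per tested gene. In data simulated at this depth and number of rats, with 200 changed genes, 45.0% of the smallest changes simulated were recovered. With fewer changed genes the share may be lower, and other depths were not simulated.

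The genes past the threshold (2 up, 0 down) numbered 0, with 0 up, under the edgeR quasi-likelihood test, limma-voom, weighted voom, log2(RPKM + 0.1) and log2(RPKM + 1). They numbered 70 (45 up, 25 down) with 1 common dispersion, 46 (26 up, 20 down) with a trended dispersion, 4 (4 up) with upper-quartile factors, 6 (4 up, 2 down) with no filter, 5 (4 up, 1 down) at a threshold of 0.10, 11 (7 up, 4 down) with 1 surrogate variable and 6 (3 up, 3 down) without Sham 1 and MI 5. Without 1 library they ranged from 2 to 8, with 2 to 6 up and 0 to 4 down; 8 passed without Sham 3 and without MI 1, 6 without MI 5 and 4 without MI 4. The 13 shifted lists ranged from 8 (without Sham 1) to 15 in the fits without 1 library, numbered 0 with an estimated correlation and 0 by fry, and numbered 10 to 16 under the other alternatives, with 16 under weighted voom and 10 without Sham 1 and MI 5.

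With the replicate number as a block 12 genes passed (5 up, 7 down). MI 5 has no same-numbered sham and had a block of its own, so it added nothing to the MI difference. Changes under this fit can therefore come from the block or from the loss of MI 5. The data gave no sign that the numbers pair the rats. Deviations of log2 CPM from the group means correlated at -0.132, -0.137, 0.036 and 0.092 between same-numbered rats. No MI rat correlated best with the sham rat of its own number. Such values cannot exclude that the rats were paired. Under the block the adjusted p was 0.0564 for calcium and HCN channels, antioxidant and oxidative stress genes, oxidative phosphorylation and peptidergic nociceptors, which lost the call. Neurohumoral receptors (0.0227) and bone and cartilage markers (0.0046) gained it. Sensory neuropeptides (0.793), sodium channels (0.793), pan-neuronal markers (0.707) and meningeal markers (0.642) turned direction.

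With an estimated correlation the adjusted p was 0.538 for interferon, complement, antioxidant and oxidative stress, peptidergic, macrophage, smooth muscle and circadian lists, 0.614 for cholesterol, 0.669 for proliferation, 0.689 for calcium and HCN channels, 0.704 for Schwann cells and 0.776 for extracellular matrix and oxidative phosphorylation. By fry it was 0.449 for interferon and antioxidant and oxidative stress genes, 0.564 for complement, cholesterol, peptidergic, macrophage, smooth muscle and circadian lists, 0.729 for calcium and HCN channels, oxidative phosphorylation, proliferation and Schwann cells, and 0.820 for extracellular matrix.

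Proliferation genes lost the call under voom (0.0599), no filter (0.0976), log2(RPKM + 1) (0.0543), 1 surrogate variable (0.0531), a mean CPM of at least 5 (0.0574) and unrounded counts (0.0503). Gains were potassium channels (0.0332), antigen presentation (0.0330) and ribosomal proteins (0.0306) under weighted voom, potassium channels (0.0800) at a threshold of 0.10, neurohumoral receptors (0.0484) and bone and cartilage markers (0.0420) with 1 surrogate variable, and neurohumoral receptors (0.0198) and antigen presentation (0.0435) at a mean CPM of at least 5. Direction turned for pan-neuronal markers under voom (0.943), upper-quartile factors (0.955), log2(RPKM + 0.1) (0.991), total counts (0.997), a mean CPM of at least 5 (0.992) and fry (0.984), for cytokines under weighted voom (0.966) and no filter (0.970), for meningeal markers under upper-quartile factors (0.967) and no filter (0.990), and for adipocyte (0.970) and sympathetic markers (0.745) under no filter.

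Without 1 library the lists' adjusted p ranged as follows. Among those shifted it was 1.52e-04 to 0.179 for calcium and HCN channels, 1.43e-07 to 0.670 for extracellular matrix, 0.0109 to 0.108 for antioxidant and oxidative stress genes, 0.00276 to 0.466 for oxidative phosphorylation, 0.0126 to 0.351 for proliferation, 2.39e-04 to 0.0700 for peptidergic nociceptors, 1.43e-07 to 0.152 for Schwann cells and 0.00561 to 0.0765 for circadian genes. Interferon, smooth muscle, macrophage, complement and cholesterol lists passed in all 9 fits. Among the others it was 0.322 to 0.915 for neuropeptides, 0.0454 to 0.308 for neurohumoral receptors, 0.132 to 0.954 for sodium channels, 0.0156 to 0.487 for potassium channels, 0.326 to 0.980 for cytokines, 0.0311 to 0.513 for antigen presentation, 0.210 to 0.968 for pan-neuronal, 0.00315 to 0.816 for non-peptidergic, 0.10 to 0.922 for lymphocyte, 0.106 to 0.968 for neutrophil and mast cell, 0.0109 to 0.917 for endothelial, 0.0120 to 0.727 for skeletal muscle, 0.364 to 0.973 for sympathetic, 0.230 to 0.968 for meningeal, 0.0120 to 0.452 for bone and cartilage and 0.109 to 0.980 for erythroid markers. It was 0.0742 to 0.674 for immediate early, 0.0244 to 0.931 for heat shock, 0.00558 to 0.801 for glucocorticoid and 3.96e-04 to 0.967 for ribosomal protein genes.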

Other observations

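The exact tests of the interferon and smooth muscle scores, the endothelial contrast with its repeats without each library, and the trended dispersion were tests chosen after the result was seen. The fit without MI 5 was fixed before, but its use as a test of the smooth muscle list was chosen after. The splits of the samples, the dispersion fixed at 0.006, the calls kept without single libraries and the macrophage covariate had their bounds set before their own results were seen, though after the tables of genes and lists had been.

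Scores of several tissue lists spread widely within both groups. Among sham rats, skeletal muscle scores ran from -0.6871 in Sham 2 to 1.3276 in Sham 3. Lymphocyte scores ran from -0.7362 in Sham 2 to 0.6275 in Sham 3. Extracellular matrix scores ran from -0.3552 in MI 4 and -0.3542 in MI 1 to 0.3586 in MI 5, and erythroid scores from -1.0109 in MI 4 to 0.4957 in MI 2. On the first principal component Sham 2, Sham 4, MI 1 and MI 4 lay above 0 and the other 5 libraries below. Groups did not overlap for 204 genes, 98 higher and 106 lower in MI, which is 1.74% of genes where chance gives 1.59%. Of all possible splits, 35 gave as many, with 495 as the highest of the others.

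Other splits of the 9 libraries did not exclude chance for the counts. Of 100 splits, 69 gave at least the 2 genes of the likelihood-ratio test, with 198 as the highest of the others and 3 as their median. With 1 common dispersion, 81 of 100 gave at least the real 70 genes, and the highest other was 450, with a median of 99. For gene lists 29 of 100 gave at least 13, and the highest other was 21, with a median of 9 lists. The split of 198 genes set Sham 2, Sham 4, MI 1 and MI 4 against the rest. It is the division along the first principal component, a structure of the samples that mixes both groups; it was picked as the highest count, and its source was not tested.

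The authors' table held 60 calls and the likelihood-ratio test 2, also when fitted, as the settings below were, on the 11811 genes before a blank line in the deposited counts, which hold all 60 where the 11711 tested above hold 54. A single dispersion of 0.006 for all genes differed from the authors' p-values by a median of 0.0658 on the log10 scale over the 7985 genes compared, between the bounds of 0.05 and 0.3 set for it and hardly closer than the tagwise fit (0.0711), with 80 calls and a p of 4.97e-71 for Fam111a against 2.12e-51 in the authors' deposited table. Of 20 dispersion settings tried, a trended dispersion with no part of each gene's own, picked afterwards, came to 0.0145 with 53 calls, 52 of them among the 60 (46 calls over the 11711 genes), which is consistent with a dispersion set by expression level alone. At a fixed 0.006, 54 of all 60 passed with all libraries, 48 of them among the 54 tested above, and 11 in all 9 fits without 1 library (20.4% of the 54 that passed, 18.3% of the 60), with 36 of those that passed kept without MI 5 and 52 without MI 3. Single libraries may carry part of the calls, as Sham 1 does for Fam111a, but fewer rats also lower the number of calls and the shares were not separated; no biological explanation was tested.

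Pericyte and smooth muscle markers were higher in MI, by a score difference of 0.36 that was matched by 4 of all possible splits (exact p = 0.0317, highest other 0.41). Adjusted over the 41 lists p was 0.434, so chance is not excluded over the lists. With so few splits no list alone could pass this adjustment, so it could not decide about chance. Without MI 5 the score difference was 0.285, so its direction did not rest on MI 5 alone, but no exact p was computed for it. The list kept a camera adjusted p of 0.00203 without MI 5, with the preset correlation only. With an estimated correlation it did not pass even with all libraries (camera adjusted p = 0.538). The kept call therefore cannot exclude that MI 5 carries much of the shift. The smooth muscle minus endothelial score was higher in MI by 0.286 (exact p = 0.00794, the smallest possible and not adjusted). The difference ran from 0.254 to 0.315 without 1 library. The smooth muscle list was picked after its shift was seen, which favours a small p. Vessels may also differ in their share of smooth muscle, so this contrast cannot exclude more vessel tissue. The endothelial score differed by 0.074 (exact p = 0.595), by 0.159 without Sham 3 and by -0.007 without Sham 4. The endothelial list passed upward without Sham 3 (camera adjusted p = 0.0109) or MI 4 (0.0209), so a gain of vessel stays open. A gain of mural or smooth muscle cells, a change of their transcription and uneven dissection of arterioles may each account for the smooth muscle difference, untested here.

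Interferon-response genes were higher in MI. The score difference of 0.25 was matched by 1 split, the real one (exact p = 0.00794, the smallest possible; highest other 0.241), but the list was the first of 41 by p and the value adjusted over them was 0.325, so chance is not excluded. By the same test circadian clock genes, a handling list, had 2 splits as large (exact p = 0.0159, adjusted 0.325). Complement genes had an exact p of 0.0952 and macrophage markers 0.119, and no list passed once adjusted. A list alone at the smallest possible p could not pass over 41 lists, so this adjustment could not decide about chance. The macrophage score did not account for the interferon difference. With that score as a covariate the difference was 0.243 (95% interval 0.035 to 0.45). Within groups the scores were related by r = 0.063. The interval takes no account of the choice of this list among 41. A marker score also measures cell number with error, so a larger number of macrophages is not excluded. An interferon response of the ganglion after MI may be the source, which was not tested.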
